A study of Mus musculus with 2 samples.

How the data were processed

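RNA from mouse bone marrow-derived macrophages was sequenced in 2 libraries, 1 from Lyz2-Cre control cells (WT) and 1 from cells lacking 3 microRNA clusters (TKO). Per the labels, marrow cells were cultured for 5 days in medium with 10% fetal bovine serum and 10% L929 supernatant, a source of macrophage growth factor, and treated with 10 ng/ml lipopolysaccharide (LPS) for 3 h. Polyadenylated RNA was taken into circularised single-stranded libraries, per the labels' protocols. Such libraries measure messenger RNA and long polyadenylated transcripts, not mature microRNAs. With 1 library per genotype the difference between genotypes has no replicate check, and genotype cannot be separated from anything else that differed between the 2 cultures.

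HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the mouse build mm10 are named per the submitters' processing notes, without the role of each. The annotation, read filters and strand setting were not given in the sources used here. Reads of near-identical genes can be divided among copies by such counting, and reads of overlapping antisense genes cannot be told apart, so genes of multicopy families and processed copies are reported as uncertain. The deposited table holds 16219 gene entries with estimated counts per library. These estimates are fractional where reads were shared between genes (79.2% were whole in the WT library and 79.4% in the TKO library), and they were rounded to whole numbers here. The authors also deposited FPKM values, in which 0.01 stands for 0. Their log2 ratio is the log2 of the TKO FPKM over the WT FPKM, per the file headers and a recomputation here. The deposited p-value and an adjusted value, treated here as a score because it reaches 1.04, come from the authors' comparison of these 2 libraries, and the test was not given in the sources used here. The deposited table's gene length column, in bases, was not used for any value here.

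No entry was at 0 in both libraries. The 1 entry without a gene symbol had 1 count in each library, a share of 9.29e-06% in WT and 9.23e-06% in TKO, and was left out, which left 16218 genes. In 23 entries the symbol had been turned into a calendar date, and the symbol was restored from the gene identifier with the RefSeq gene table of assembly GRCm38.p6, in which 16179 identifiers were found. Coordinates came from GENCODE release M21, the same GRCm38/mm10 assembly, for 15111 genes, of which 14770 had an annotated 3' UTR. The microRNA genes' positions came from the RefSeq table.

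Total rounded counts were 10764519 for WT and 10836855 for TKO, with at least 1 count for 15358 and 15295 genes. The most abundant transcript took 1.61% of the WT count and 1.75% of the TKO count, and the 10 most abundant took 6.85% and 7.17%. A count of 0 was read against a floor of 3 counts per library, which is 0.279 CPM in WT and 0.277 CPM in TKO. CPM, the count per 1000000 counts of the library total, was computed for each gene, and genes with a mean of at least 1 CPM over both libraries were taken as measured. Log2 ratios are log2 of (TKO CPM + 0.5) over (WT CPM + 0.5), which understates the differences of low genes. Folds in the text are ratios of CPM without that addition, followed by the 95% counting interval (exact Clopper-Pearson, conditional binomial). A fold against a count of 0 is given as a lower limit against the floor. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A gene was called at least 2-fold apart when its log2 ratio was at least 1 in size and its interval excluded equality.

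No test across replicates was possible and no p-value was computed. For each of 40 gene lists (866 genes: pathways, cell types and complexes) the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, drawn for each member from the 100 genes nearest in mean CPM. The percentile describes these 2 libraries. A list was said to stand apart when its median lay outside the central 95% of its random lists. Lists with fewer than 5 measured members were given member by member. List members were counted as higher or lower at 1.5-fold with an interval excluding equality.

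MicroRNA target sets were the genes with at least 1 match to a seed (7 bases, opposite microRNA bases 2 to 8) in the longest annotated 3' UTR. The 4 seed families of the deleted clusters were compared with 8 other families. Each set's median was placed among 10000 random lists drawn in 10 by 10 classes of mean CPM and 3' UTR length. They were drawn from genes with no site of any deleted family and, for the other families, no site of their own. The sets themselves kept genes that also had sites of further families. It was also ranked among the medians for all anagrams of the site that lack CpG and are found in at least 100 genes. Intervals of medians are 95% order-statistic intervals over genes, which are not independent replicates.

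Named genes followed a fixed rule. It took the cluster host genes, the 12 genes farthest apart in each direction by the interval bound nearest to equality, up to 4 members of each list by the same bound where the interval excluded equality, 10 genes of inflammation and of known microRNA regulation whatever their values, and the 6 genes highest by that bound with sites for at least 2 of the deleted families. Genes named outside this rule are said to be chosen after their values were seen. The results of a few genes that the rule names are not reported here. The groups, the ratio and its interval, the gene lists, the seed sites, the rule for named genes and most alternatives were set before the data were examined.

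The alternatives were edgeR 4.0.16 TMM factors (1.02 for WT, 0.983 for TKO), DESeq2 1.42.0 size factors (1.01 and 0.988), the authors' FPKM, pseudocounts of 0.1 and 2 CPM, no abundance filter, a mean of at least 10 CPM, no counting interval, a bound of at least 2-fold, the authors' calls, sites of 8 bases, at least 2 sites, random lists matched on GC content too, sets without the genes 2-fold apart, and lists without shared members. Leaving out chromosome 17, leaving out stromal and collagen genes, and drawing random lists from genes without the family's own site were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.

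The procedure was tested on data simulated from the WT and TKO means and library sizes over 11658 measured genes, with 50 genes at each of 4 known folds. These changed genes were drawn from those with a pooled level of at least 5 CPM. The calling of changed genes below that level was not tested. The rule for 2-fold genes called 0 of 50 genes simulated at 1.5-fold, 19 of 50 at 2-fold, and all 50 each at 3-fold and 4-fold, with 0 in the wrong direction. It called 14 of 11458 unchanged genes (0.122%), and 94.8% of the unchanged genes had intervals that held equality. The intervals held the simulated ratio for 48 of 50 genes at 1.5-fold, 48 at 2-fold, 47 at 3-fold and 44 (88%) at 4-fold, below the nominal 95% for the last. In a run over 11662 genes, a list shifted by 1.3-fold was at percentile 0, and 3 of 34 unshifted lists stood apart. A log2 shift of 0.05 in a seed set was recovered as 0.0465 over 11675 genes, and 0 of 12 unshifted seed sets stood apart over 11676 genes. Simulated counts carry counting error only, so these shares do not measure differences between cultures of one genotype.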

Results

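Polyadenylated RNA of mouse bone marrow-derived macrophages was measured 3 h after addition of LPS, the bacterial cell wall component that activates Toll-like receptor 4. The WT library came from cells carrying Lyz2-Cre, which drives recombination in myeloid cells. The TKO library came from cells lacking 3 related microRNA clusters: mir-106b~25, the X-linked cluster that runs from mir-106a to mir-363 and, through the same Cre, mir-17~92. Each genotype had 1 library, with 10764519 counts for WT and 10836855 for TKO, and no unstimulated library was analysed here. The comparison asks how the messenger RNA of LPS-treated macrophages differed without these clusters, and whether transcripts with sites for their microRNAs were higher. With 1 library each, every difference below has no replicate check, and "higher" or "lower" describes these 2 libraries.

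The TKO library had less Il10, the main anti-inflammatory cytokine of macrophages, and more Il12b, which encodes the p40 subunit of IL-12 and IL-23. Il10 was 3.53-fold lower (2.94 to 4.25) and Il12b 2.70-fold higher (2.57 to 2.83), while Tnf was only 1.11-fold higher (1.09 to 1.13). Feedback inhibitors of inflammation, collagens and other stromal transcripts, glycolytic genes and proliferation genes were lower as groups. Interferon-response, MHC class II and oxidative-stress genes were higher as groups against matched lists. The intervals of the interferon-response (−0.0038 to 0.14) and class II (−0.38 to 0.97) medians included 0. The farthest single genes were class I genes of the major histocompatibility complex (MHC), with H2-L 489-fold higher (296 to 873). Transcripts with a site for the miR-17 seed family had a median log2 ratio only 0.0544 above that of matched lists.

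The deleted loci were examined first. The microRNA genes lie on chromosome 14 at 115043671 to 115044506 for mir-17~92 (6 genes), chromosome 5 at 138165321 to 138165818 for mir-106b~25 (3 genes) and chromosome X at 52741693 to 52742567 for the X-linked cluster (6 genes), in GRCm38.p6 coordinates. None of these microRNA genes has an entry among the genes analysed here. The primary transcript of mir-17~92, Mir17hg (gene 75957), had 16 counts in each library, a ratio of 1.01 (0.471 to 2.15). Mcm7 (gene 17220, chromosome 5, 138164583 to 138172422), a replication helicase gene whose span holds mir-106b~25, had 608 counts in WT and 496 in TKO, 1.23-fold lower (1.09 to 1.39). A count over a whole host gene does not show whether the part encoding the microRNAs was removed, so these values do not check the labels. Among 12 measured neighbours of the clusters the median log2 ratio was −0.25, at percentile 3.21 of matched lists. Pcolce was 3.90-fold lower (2.22 to 7.24), Gpc4 had 18 against 5 counts, Zfp113 was 1.62-fold higher (1.34 to 1.96) and Cops6 was 1.21-fold lower (1.07 to 1.37). With the authors' FPKM this list was at percentile 1.57.

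Of 11662 measured genes, 119 were at least 2-fold higher in the TKO library and 196 at least 2-fold lower, while 90.1% lay within 1.5-fold of equality. The median log2 ratio was −0.04 with a standard deviation of 0.43 over genes, and log2 CPM values of both libraries had a Pearson correlation of 0.982 across genes, which are not independent replicates. These counts depended on low-abundance genes: at a mean of at least 10 CPM, 49 genes were higher and 72 lower. Requiring the interval bound itself to be 2-fold left 54 and 56. In the authors' deposited table, which compares these 2 libraries and not the conditions, 156 genes were higher and 274 lower at an adjusted value of at most 0.05 and 2-fold.

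**Figure D1:**
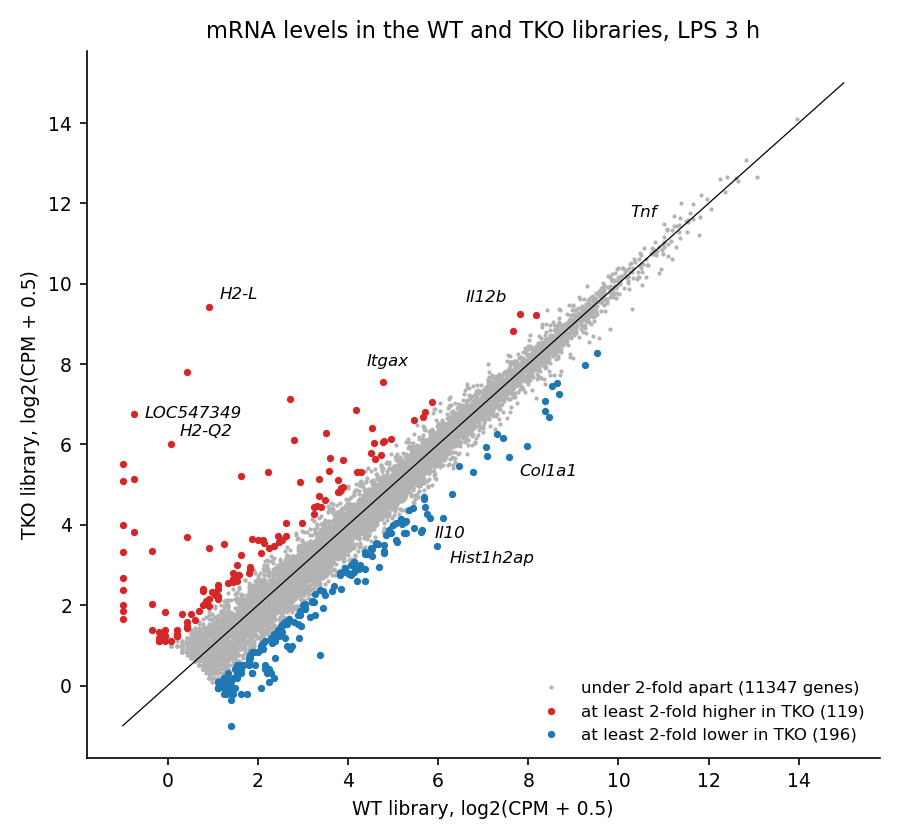
Each point is 1 of the 11662 measured genes, with its level in the WT library on the horizontal axis and in the TKO library on the vertical axis, both as log2(CPM + 0.5). The 119 genes at least 2-fold higher in TKO are red and the 196 at least 2-fold lower are blue; the line marks equality.

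Among 30 measured pro-inflammatory cytokines and chemokines, 6 were at least 1.5-fold higher in TKO and 4 lower, so that the list's median log2 ratio was 0.05 (percentile 89.7). Il12b (gene 16160, chromosome 11, 44400063 to 44414033) had 2413 counts in WT and 6550 in TKO. Il12a, the partner subunit of IL-12, was 2.29-fold higher (1.5 to 3.55). Of the chemokines, Cxcl11 was 2.81-fold higher (2.42 to 3.25), and the neutrophil attractants Cxcl1 and Cxcl3 were 2.23-fold (2.12 to 2.34) and 1.92-fold (1.85 to 2.00) higher. The chemokine gene Ccl4 was 1.89-fold lower (1.83 to 1.94), and so were Tnfsf9 (1.61-fold), Il27 (1.60-fold) and Ccl2 (1.51-fold). Il12a and these 4 lower genes were chosen after their values were seen. Il6 was 1.34-fold higher (1.25 to 1.42) and Il1b 1.03-fold higher (1.01 to 1.06). Ifnb1 had 6 and 9 counts, a difference not detectable at this depth (ratio 1.49, 0.474 to 5.09). Of 22 inflammatory effectors, the scavenger receptor Marco was 3.54-fold higher (2.84 to 4.44), and 3 were lower, including Hdc (2.01-fold) and Vcam1 (1.68-fold). That list's median was −0.13, at percentile 2.08, and at percentile 6.38 without the abundance filter. Nos2, which encodes inducible nitric oxide synthase, was 1.06-fold lower (1.02 to 1.1).

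**Figure D2:**
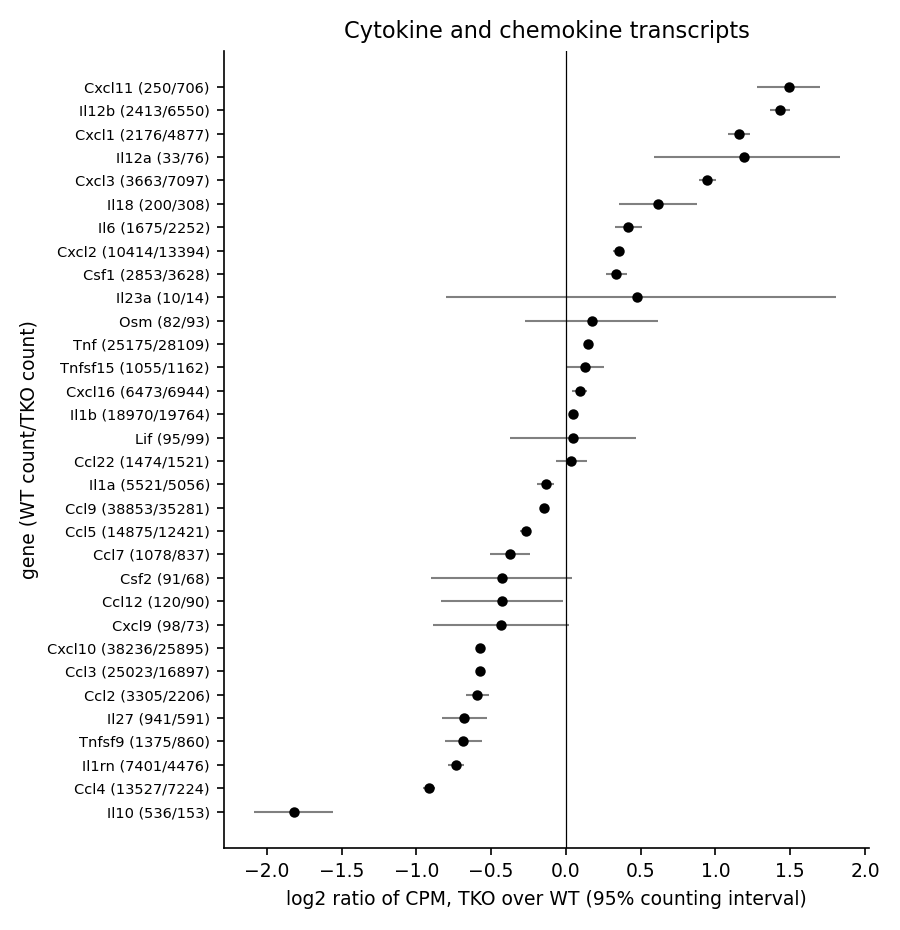
Points show the log2 ratio of CPM, TKO over WT, for 30 cytokine and chemokine genes with Il10 and Il1rn added, and bars show 95% counting intervals. WT and TKO counts stand beside each gene; Il10 lies farthest to the left at 536 and 153 counts, and Cxcl11 and Il12b farthest to the right.

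Il10 (gene 16153, chromosome 1, 131019845 to 131024974) belongs to a list of 33 anti-inflammatory and feedback genes, of which 10 were at least 1.5-fold lower in TKO and 1 higher. The list's median log2 ratio was −0.24, below all 10000 matched lists. The IL-4 receptor chain Il4ra was 2.44-fold lower (2.30 to 2.60), the repressor Sbno2 1.96-fold lower (1.86 to 2.06) and Zfp36, which encodes an mRNA-destabilising protein, 1.94-fold lower (1.87 to 2.00). The exception, the MAP kinase phosphatase gene Dusp4, was 1.75-fold higher (1.56 to 1.96) and was chosen after its value was seen. The interferon-response list went the other way, with 4 of 44 members at least 1.5-fold higher, 0 lower and a median of 0.09 (percentile 99.4). Its members farthest apart were Ifit3b (1.74-fold higher, 1.58 to 1.91), the nucleic acid sensor Zbp1 (1.62-fold, 1.51 to 1.72), Oas3 (1.51-fold, 1.44 to 1.58) and Ifi44 (1.59-fold, 1.39 to 1.82). Of 44 genes of Toll-like receptor, NF-κB and MAP kinase signalling, 1 was 1.5-fold apart, Fos at 3.20-fold lower (2.39 to 4.36), and the median was 0.00 (percentile 68.2). Among 21 immediate-early and heat shock genes, Fos, Fosl1 (2.01-fold) and Ier3 (1.60-fold) were lower and 0 higher, with a median of −0.12 (percentile 9.68).

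Macrophage identity genes were close to equality. Of 31 measured, 1 was 1.5-fold apart, the lipid scavenger receptor gene Cd36 (1.55-fold lower, 1.47 to 1.63), and the median was −0.04 (percentile 14.0), with a sign that turned under TMM scaling. Lyz2, whose promoter drives the Cre, had 576 and 676 counts and was chosen after its values were seen. Of 16 genes of alternative activation, Il4ra, Fn1 (2.42-fold, 2.23 to 2.64) and the nuclear receptor gene Pparg (1.87-fold, 1.22 to 2.91) were lower and 0 higher. The median of −0.37 (percentile 0.03) rested on low-abundance members, since it was −0.05 (percentile 34.0) at a mean of at least 10 CPM. For 26 complement, Fc receptor and phagocytosis genes the median was −0.04 (percentile 21.2), with Marco and C3 (1.60-fold, 1.54 to 1.66) higher and Cd36 lower. Of 15 chemokine and chemoattractant receptor genes, Fpr2 was 1.61-fold higher (1.36 to 1.92), and 3 were lower, including Ccr3 (4.03-fold, 2.41 to 7.05) and Ccr1 (95 and 57 counts, chosen after its values were seen). The median of that list was 0.23 (percentile 99.9), although more of its members were 1.5-fold lower than higher.

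Markers of other cells were mostly near the floor. Of 18 neutrophil markers 7 were measured, with a median of −0.02 (percentile 61.6) and S100a9 at 21 and 8 counts. Of 16 T and NK cell markers 6 were measured (median −0.28, percentile 14.2), Lck with 32 and 10 counts. The 2 measured B cell markers were Blnk (1607 and 1723 counts) and Cd22 (92 and 125 counts). The 2 measured mast cell, basophil and eosinophil markers were Kit (15 and 9 counts) and Siglecf (27 and 17 counts). The 3 measured erythroid and megakaryocyte genes were Car2 (45 and 25 counts), the transferrin receptor gene Tfrc (547 and 354 counts) and Pf4 (273 and 299 counts). Blnk, Kit, Siglecf and Pf4 lie outside the rule for named genes and were chosen after their values were seen, because so few members were measured. Dendritic cell markers had a median of 0.48 over 7 members (percentile 100), but with an interval of −0.66 to 2.76 and values of 0.298 to 0.528 under alternative processing. Of the 7, 2 were at least 1.5-fold higher: Itgax, the CD11c integrin gene (gene 16411, chromosome 7, 128129547 to 128150657), was 6.89-fold higher (6.09 to 7.82), and H2-DMb2, a gene of the MHC region, had 3 and 39 counts. The neighbouring integrin gene Itgad had 0 and 64 counts and was at least 21.2-fold higher. The 8 measured MHC class II genes had a median of 0.28 (percentile 99.9), but with an interval of −0.38 to 0.97, and 2 were at least 1.5-fold higher. H2-DMa was 1.67-fold higher (1.3 to 2.16), H2-Eb1 1.39-fold higher (1.2 to 1.61), Cd74 1.17-fold higher (1.11 to 1.23) and H2-DMb1 1.31-fold lower (1.11 to 1.54). Of these, all but Cd74 lie in the MHC region of chromosome 17, where class I genes differed strongly. Of 6 measured sex-linked genes 0 were 1.5-fold apart by the log2 ratio (median 0.12, percentile 92.0), although Tsix was 1.51-fold higher (1.21 to 1.89) by CPM alone. Xist had 3792 and 3844 counts and the Y-linked gene Eif2s3y 0 and 2, both chosen after their values were seen.

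MHC class I genes made up most of the genes farthest higher in TKO. After H2-L (15 and 7378 counts) came LOC547349, a class I-like gene with 1 and 1165 counts (1157-fold higher, 207 to 45747). H2-Q10 had 1 and 376 counts (373-fold, 66.6 to 14791), H2-Q2 6 and 692 (115-fold, 52.4 to 313) and H2-Q1 1 and 148 (147-fold, 26.0 to 5845). Gm8909 and H2-T9, at 0 counts in WT, were at least 164-fold and at least 122-fold higher. The class II pseudogene H2-Ea-ps, also at 0 in WT, was at least 55.3-fold higher. Of 33 measured class I family members by the orthology in the deposited table, 15 were at least 2-fold higher and 0 at least 2-fold lower. Some members were lower by less, beyond counting error, such as H2-Q7 (289 and 149 counts) and H2-T10 (292 and 173 counts), chosen after their values were seen. That orthology group is wider than the MHC: 5 of the 33, such as Hfe and Fcgrt (chosen after their values were seen), lie on other chromosomes, and 0 of these 5 were 2-fold apart. The abundant classical genes H2-D1 (22089 and 20964 counts) and H2-K1 (12153 and 13609 counts), chosen after their values were seen, lay close to equality. Class I genes are near-identical copies among which reads can be divided, so single values are uncertain, but the summed count of the orthology group was also 1.38-fold higher (1.36 to 1.39), at 45689 in WT and 63357 in TKO. Also in the top group, Atp6v0c-ps2, a copy of another gene, was 267-fold higher (140 to 585), a value uncertain for the same reason. In that group, 0610010B08Rik had 0 and 103 counts and was at least 34.1-fold higher.

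**Figure D3:**
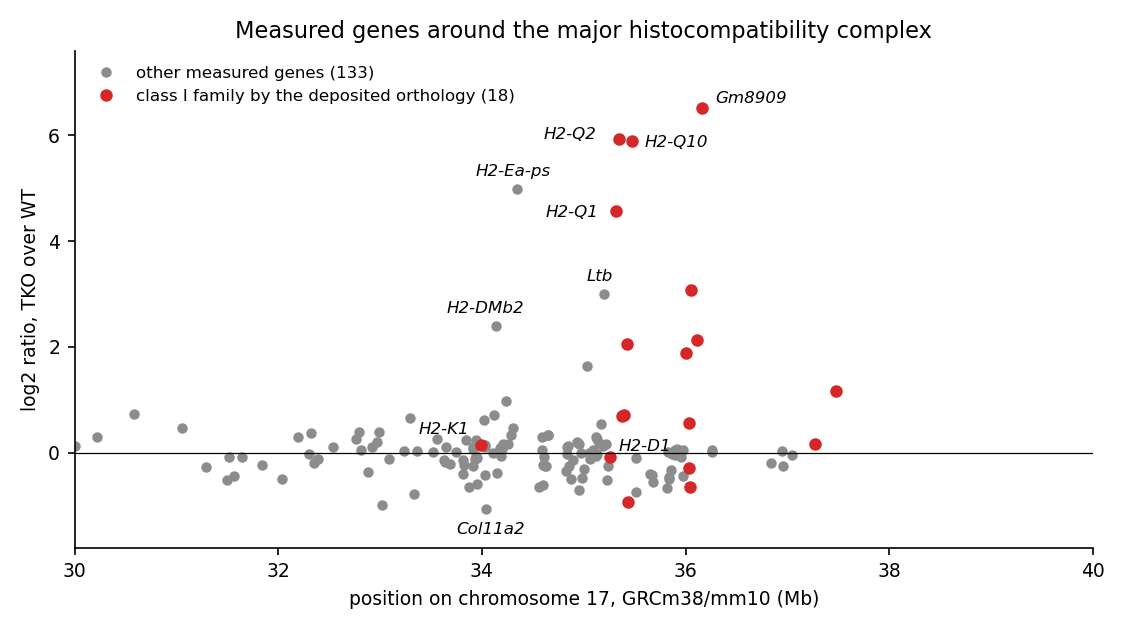
The log2 ratio, TKO over WT, of measured genes is plotted against position on chromosome 17 from 30 to 40 Mb (GRCm38/mm10), with 18 class I family genes in red and 133 other genes in grey. Several red points, and the class II genes H2-Ea-ps and H2-DMb2 among the grey ones, lie far above 0, and most other genes lie near 0; genes without coordinates, such as H2-L, are not shown.

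Stromal transcripts were lower in TKO. Of 16 measured fibroblast and stromal markers, 10 were at least 1.5-fold lower and 0 higher, and the median log2 ratio was −0.96, below all 10000 matched lists. Col1a1 (gene 12842, chromosome 11, 94936224 to 94953042), the major fibrillar collagen, was 3.76-fold lower (3.42 to 4.14), with 2055 and 550 counts. Col1a2 was 2.74-fold (2.45 to 3.07), Col3a1 3.64-fold (2.72 to 4.93) and Postn 3.45-fold (2.68 to 4.50) lower. Beside these, the metalloprotease inhibitors Timp3 (3.91-fold, 3.33 to 4.61) and Timp1 (3.60-fold, 2.99 to 4.35) were among the 12 genes farthest lower. Of 30 adhesion, matrix and protease genes, 6 were at least 1.5-fold lower, with Fn1 and the urokinase gene Plau (2.08-fold, 1.71 to 2.54) among them, and 2 higher, including Itgb7 (1.75-fold, 1.58 to 1.95, chosen after its value was seen). That list's median was −0.04 (percentile 27.0). Of 26 TGF-β and BMP pathway genes, 5 were lower, including Ctgf (2.13-fold, 1.68 to 2.72) and Id1 (1.93-fold, 1.46 to 2.56), and the receptor gene Tgfbr2 was higher (1.86-fold, 1.71 to 2.03). The median of −0.19 (percentile 0.6) was −0.06 (percentile 23.0) at a mean of at least 10 CPM. The 7 measured osteoclast markers had a median of −0.47 (percentile 0.55), 2 of them at least 1.5-fold lower: Mmp9 (2.39-fold, 1.59 to 3.65) and Dcstamp (21 and 7 counts).

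Metabolic and growth genes were lower by smaller amounts. Among 28 hypoxia and glycolysis genes, 26 had log2 ratios below 0 and 4 were at least 1.5-fold lower, with 0 higher, a median of −0.28 and percentile 0. Pfkfb3, which makes the activator of phosphofructokinase, was 2.88-fold lower (2.70 to 3.07). Hk2, which encodes hexokinase 2, was 1.83-fold lower (1.70 to 1.98), Bnip3 1.97-fold lower (1.68 to 2.32), and Ankrd37 had 21 and 5 counts. Among 39 cell cycle genes, 36 were below 0 and 4 at least 1.5-fold lower, with a median of −0.35 (percentile 0). Aurka, a mitotic kinase gene, was 1.68-fold lower (1.44 to 1.95), Ccne1 1.95-fold (1.36 to 2.83) and Tk1 1.57-fold (1.31 to 1.89). With scaling by total count, all 34 ribosomal protein genes were below 0, 0 of them by 1.5-fold, with a median of −0.15 (percentile 0), which was −0.10 with TMM scaling. For 30 nuclear genes of oxidative phosphorylation the median was −0.11 (percentile 1.68), and 0 were 1.5-fold apart. Genes encoded by mitochondria were not among the measured genes. The 5 measured replication histone genes had a median of −0.26 (percentile 4.68), with Hist2h2aa1 at 40 and 15 counts. Hist1h2ap, another histone gene of a near-identical family, was 5.89-fold lower (4.82 to 7.25).

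Stress, lysosome and lipid lists were higher. For 18 NRF2 and oxidative stress genes the median was 0.19 (percentile 100): Srxn1, which encodes sulfiredoxin, was 1.59-fold higher (1.48 to 1.71), but the metallothionein genes Mt1 (2.00-fold, 1.88 to 2.12) and Mt2 (2.45-fold, 2.34 to 2.56) were lower. For 26 lysosome and autophagy genes it was 0.13 (percentile 99.8), with the autophagy receptor gene Sqstm1 1.55-fold higher (1.53 to 1.57). Without members shared with other lists, the lysosome list was at percentile 97.2. For 17 endoplasmic reticulum stress genes it was 0.11 (percentile 98.2), with Ddit3, which encodes CHOP, 1.95-fold higher (1.52 to 2.53). For 26 cholesterol and lipid genes it was 0.07 (percentile 98.4), with 2 at least 1.5-fold higher, Nr1h3 (1.83-fold, 1.47 to 2.28) and Mylip (1.70-fold, 1.47 to 1.98), and 2 lower, Cd36 and Lpl (1.56-fold, 1.53 to 1.59).

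**Figure D4:**
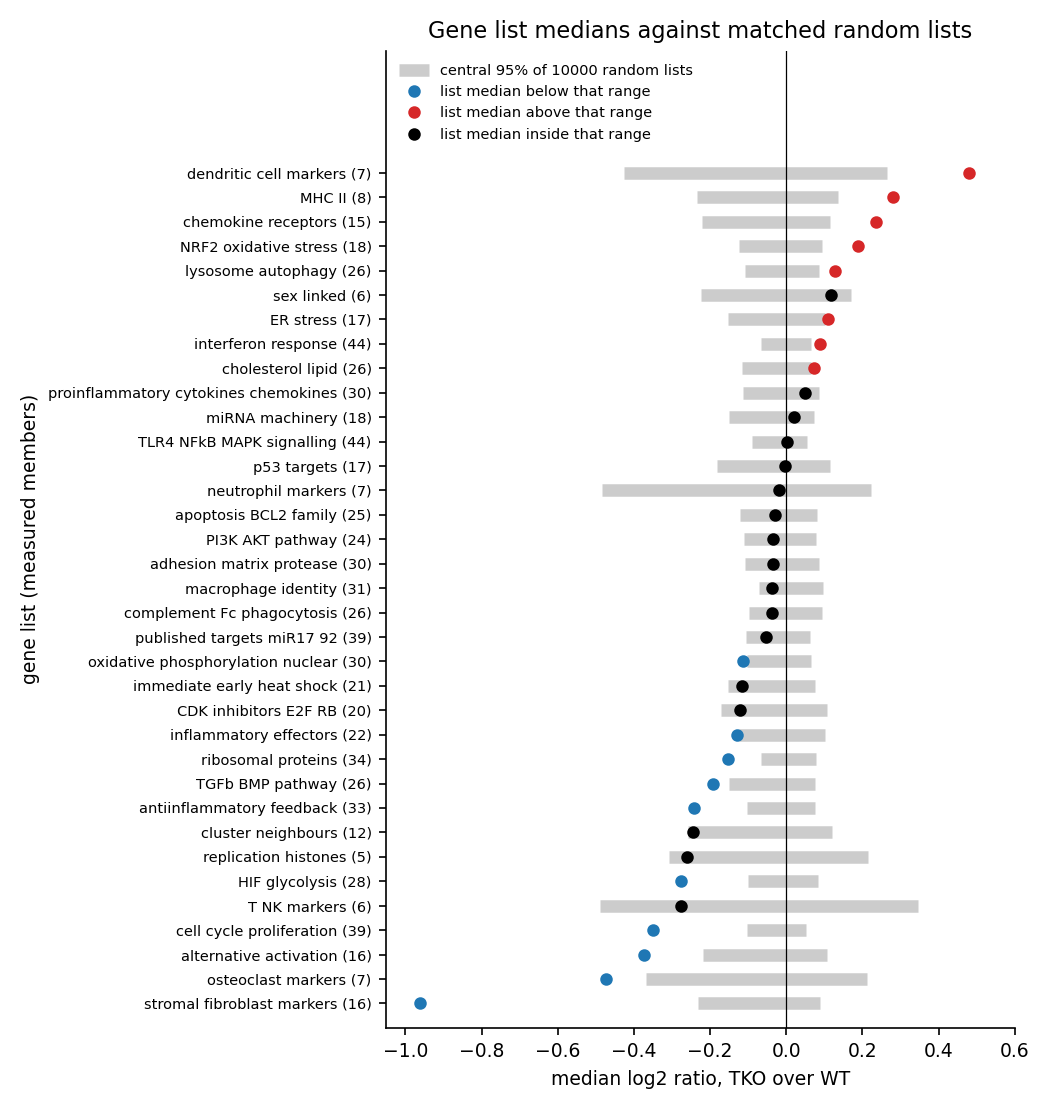
Points give the median log2 ratio, TKO over WT, of each gene list with at least 5 measured members, and grey bars the central 95% of 10000 random lists matched on mean CPM. Blue points, with the stromal list lowest at −0.96, lie below their bars, and red points, with the dendritic cell markers highest at 0.48, lie above them.

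Other regulatory lists were near equality, and the signs of their medians are not read because scaling turned some of them. Of 25 BCL2 family and apoptosis genes 0 were 1.5-fold apart (median −0.03, percentile 46.1), and the proapoptotic Bcl2l11, an established target of these microRNAs, was 1.07-fold lower (1.02 to 1.12). Of 24 PI3K pathway genes 0 were 1.5-fold apart (median −0.03, percentile 31.5). The CDK inhibitor gene Cdkn1a was 1.04-fold higher (1.02 to 1.07). Of 20 CDK inhibitor, E2F and RB genes, 1 was higher and 3 lower, including Cdkn2d (1.96-fold, 1.55 to 2.48) and E2f8 (1.52-fold, 1.32 to 1.75), with a median of −0.12 (percentile 9.65). Without members shared with other lists that median was −0.35 (percentile 0.1). For 17 p53 targets it was 0.00 (percentile 66.4), with 2 higher, including Gdf15 (2.10-fold, 1.39 to 3.24), and 1 lower, Phlda3 (2.2-fold, 1.19 to 4.26). For 18 genes of microRNA processing and function it was 0.02 (percentile 84.2), and 0 were 1.5-fold apart.

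Transcripts with 3' UTR sites for the deleted families were compared last. The 1728 genes with a miR-17 site (GCACTTT) had a median log2 ratio of 0.01 (−0.00334 to 0.0228), which was 0.0544 above the median of lists matched on abundance and 3' UTR length and above all 10000 of them. It also exceeded all 298 anagrams of the site. The 1579 genes with a miR-19 site and the 892 with a miR-92 site lay 0.0316 and 0.0366 above their matched lists, at percentile 100 in both cases, but 43 of 298 and 23 of 449 anagrams had medians as high. The 1165 genes with a miR-18 site lay 0.0104 above (percentile 91.0), and 152 of 239 anagrams were as high. Of 8 families outside the clusters, the offsets reached 0.0401 for miR-146 and 0.0360 for miR-21. Their sets kept genes with sites of the deleted families, which their random lists left out, so part of these offsets can come from that choice. When the random lists were drawn from all genes without the family's own site, chosen after seeing the data, miR-19 lay 0.0134 above (percentile 95) and miR-18 −0.0102 from its lists. The median log2 ratio was −0.06 for 7133 genes with a site of none of the deleted families, −0.03 for 2916 with 1 family, 0.02 for 885 with 2, 0.04 for 186 with 3 and 0.02 for 30 with 4.

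**Figure D5:**
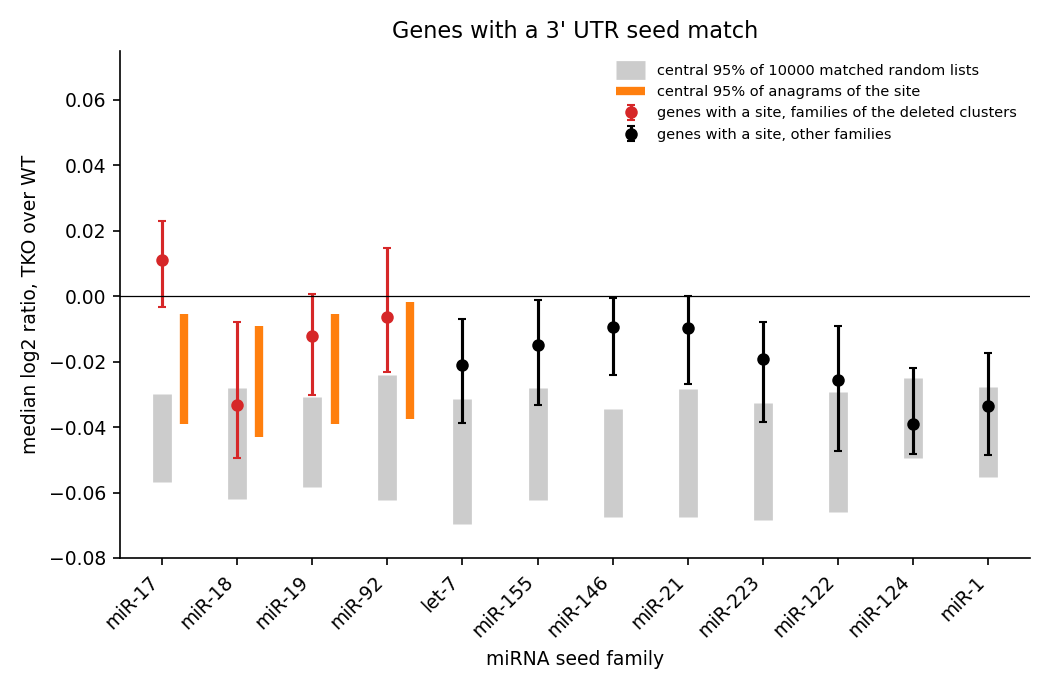
Points give the median log2 ratio, TKO over WT, of genes with a 3' UTR seed match for each family, with 95% order-statistic intervals, in red for the 4 families of the deleted clusters and black for 8 others. Grey bars are the central 95% of matched random lists and orange bars that of anagrams of the site; the miR-17 point alone lies above both of its bars.

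Of genes with sites for at least 2 of the deleted families, those farthest higher were Cers4, a ceramide synthase gene (7.35-fold, 4.27 to 13.6), Peg10 (5.96-fold, 3.69 to 10.1), Bhlhe41 (2.47-fold, 2.12 to 2.89), Cd69 (2.06-fold, 1.98 to 2.15), Rgs1 (2.05-fold, 1.73 to 2.43) and Tgfbr2. Other genes of this class were lower, such as Pfkfb3, Ccr3, Bnip3 and Ctgf, given above. Of 39 measured genes named in the literature as targets of these clusters, 6 were at least 1.5-fold higher and 1, Ctgf, lower. Nabp1 was 2.63-fold higher (2.09 to 3.32), and Tgfbr2, Mylip and Sqstm1 were given above. The list's median of −0.05 (percentile 18.0) did not stand apart, and it was 0.04 (percentile 82.3) without members shared with other lists.

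Other genes among the 12 farthest lower were the small GTPase gene Rnd1 (4.05-fold, 3.72 to 4.42), the noncoding transcript U90926 (8.21-fold, 4.6 to 15.9), the retinoic acid synthesis gene Aldh1a3 (7.72-fold, 3.29 to 22.1) and Nanos1 (7.19-fold, 3.24 to 18.8). Gm14391, a member of a zinc finger family of similar copies, had 40 and 5 counts. Gm9833 had 23 and 0 counts and was at least 7.72-fold lower.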

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

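No paired analysis was possible because each genotype has 1 library. Tests chosen only after seeing the data were leaving out chromosome 17, leaving out stromal and collagen genes, and random lists from genes without the family's own site. No value changed its sign among the called results. The counts of genes at least 2-fold apart (119 higher and 196 lower) stayed within 1.5 times with TMM (131 and 175), DESeq2 size factors (122 and 179), a pseudocount of 0.1 CPM (144 and 266), no abundance filter (166 and 281), no counting interval (119 and 196), the authors' deposited table (156 and 274), without chromosome 17 and genes lacking coordinates (82 and 176) and without stromal and collagen genes (119 and 181). They were lower by more at a pseudocount of 2 CPM (63 and 78) and at a mean of at least 10 CPM (49 and 72), where low genes are shrunk or left out. They were also lower when the bound itself had to be 2-fold (54 and 56), and with the authors' FPKM the count of lower genes was 106, beside 87 higher; the cause of the last was not tested. Of the list medians under alternatives, 274 stayed within their intervals and 1 moved: hypoxia and glycolysis with TMM, at −0.23. Inflammatory effectors, alternative activation, the TGF-β pathway and the lysosome list each lost their place outside the central 95% under 1 alternative. Of the log2 ratios of named genes, 722 stayed within their counting intervals and 58 moved. Of the seed set offsets, 44 stayed. The miR-17 offset was 0.0362 without an abundance filter, 0.0785 with sites of 8 bases and 0.106 with at least 2 sites. The miR-92 offset was 0.0802 with 8 bases and 0.117 with at least 2 sites, and the miR-19 offset was 0.0559 with at least 2 sites. Families outside the clusters also rose, to 0.0704 for miR-21 with 8 bases and 0.0740 for miR-223 with at least 2 sites. With lists from genes without the family's own site, the miR-18 and miR-19 offsets were −0.0102 and 0.0134. For the seed offsets the cause was not tested. Depth limits low genes most: differences between values that are both near 3 counts could not be detected here.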

Other observations

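The gene groups described by position, and the genes named with them, were chosen after their values were seen. The tests chosen only after the result was seen were those of a strain segment, of the summed class I count, of fewer stromal cells, of the matrix set, of the IL-10 and STAT3 response, of ERK output, and the split of the 3' UTR composition test by family. With that split, a set also had to exceed its anagrams and the families outside the clusters. These added requirements were chosen after the result was seen too. The tests of the deleted seed families and of B cells were written before their results were seen.

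Among windows of 5 Mb, that of chromosome 17 from 35 to 40 Mb held the most genes at least 2-fold apart, 11 of 59 measured, mostly class I genes. When the calls were shuffled among genes 1000 times, the fullest window held 7 at the 95th percentile and 11 at most. All other windows held 5 or fewer, inside what shuffling gave. The next were chromosome 2 from 175 to 180 Mb, with 5 of 22, and chromosome 5 from 135 to 140 Mb, with 5 of 83, against 2.54% of all measured genes with a position. Those on chromosome 2 went both ways: 0610010B08Rik, Gm14326 (22 and 58 counts) and Gm14440 (9 and 25) were higher, and C330013J21Rik (4419 and 1659) and Gm14391 lower. Shares closer to the overall one were found in 2 windows with myeloid receptor and integrin genes. On chromosome 17 between 45 and 50 Mb, 3 of 64 measured genes were at least 2-fold apart: Trem1 (3.50-fold, 2.86 to 4.31), Treml4 (2.83-fold, 2.11 to 3.86) and Trem3 (4 and 18 counts), all higher. On chromosome 7 between 125 and 130 Mb, 4 of 93 measured genes were at least 2-fold apart: Gdpd3 (3 and 104 counts, 34.4-fold, 11.5 to 170), Itgax and Itgad were higher and Il4ra was lower. Within 1000 kb of mir-106b~25 on chromosome 5, 5 of 36 measured genes were at least 2-fold apart (13.9%). The shuffle does not cover this unit; of 10574 runs of 36 neighbouring measured genes, overlapping ones included, 98 (0.927%) held at least as many, a comparison made after the count was seen. The paired immunoglobulin-like receptor genes Pilra (2.46-fold, 2.14 to 2.82), Pilrb1 (3.09-fold, 1.97 to 5.02) and Pilrb2 (2.89-fold, 2.02 to 4.2) were higher, and Pcolce and Pdgfa (2.89-fold, 2.21 to 3.80) lower. Within the same distance of the X-linked cluster, 1 of 8 genes was, Gpc4, and 17.4% of runs of 8 genes held at least as many.

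Lower Il10 beside higher Il12b raised the hypothesis that the IL-10 and STAT3 feedback response was weaker in the TKO library. A list of 12 response genes was written after the cytokine values were known, without Il10, Il4ra, Sbno2 and Zfp36. These 12 genes had a median log2 ratio of −0.69, at percentile 0 of matched random lists. Of these, 7 were at least 1.5-fold lower, among them Tnip3, Etv3 (4065 and 2284 counts), Nfil3 (377 and 223), Il1rn (7401 and 4476) and Bcl3 (2310 and 1416), while Il21r (495 and 489) and Il10ra (2275 and 2397) were not lower beyond counting error. Since 6 of the 12 also belong to the feedback list already described, the other 6 were taken alone, and their median was −0.54 (percentile 0.01), 5 of them lower beyond counting error. These values are consistent with a weaker IL-10 and STAT3 feedback response, in 1 library pair and with no measure of IL-10 protein or STAT3 phosphorylation. The alternative of a weaker ERK pathway output, which also feeds Il10, cannot be told apart from it. The 13 measured ERK output genes had a median of −0.20 at percentile 12.55, inside the range of random lists. Their list left out genes already seen to be lower, such as Fos, Fosl1 and Ier3. Of the 13, 5 were lower beyond counting error, among them Spred1 (4229 and 3006 counts) and Dusp6 (93 and 52 counts), and 2 were higher, Dusp4 included.

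Genes with miR-17 sites lay above their matched lists, by 0.0481 (0.0339 to 0.0600) with GC content matched too. That offset exceeded those of all 8 other families run the same way, but its interval overlapped that of the highest, miR-146 (0.0400, 0.0253 to 0.0489). The set's median also exceeded those of all 298 anagrams of the same bases, which were not matched on abundance or 3' UTR length. These values go against 3' UTR base composition as the whole cause without excluding it. The miR-19 and miR-92 sets also stayed above their GC-matched lists, by 0.0256 and 0.0299 (percentiles 99.93 and 99.98). The composition rule written beforehand asked only that offsets stay outside the central range of GC-matched lists. Under that earlier rule, the miR-19 and miR-92 sets would also have gone against composition. The comparisons with anagrams and with other families were added later. Of the 8 families outside the clusters, 6 lay above the central 95% of such lists too, and let-7 (0.0317) and miR-146 had larger offsets. The sets of these families kept genes with sites of the deleted families, while their random lists left such genes out. Their offsets therefore cannot show whether 3' UTR composition gave those of miR-19 and miR-92, and for these 2 sets composition stays open. Loss of the deleted microRNAs' seed families may account for the miR-17 offset. Under the rule written for that explanation, all 4 member sites had to rank in the top 5% of their anagrams. Only the miR-17 site did: the miR-92 site was at percentile 94.9, miR-19 at 85.6 and miR-18 at 36.4. The amounts of the mature microRNAs were not measured, so the rank each family should reach is not known. The lower ranks therefore leave the explanation open. With 1 library per genotype it cannot be told apart from another difference between the cultures that goes with 3' UTR sequence.

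The tables argue against reads passed between class I copies with an unchanged total as the whole cause of the MHC pattern, since the family's sum was 1.38-fold higher (1.36 to 1.39). Reads divided differently beside a higher total were not tested for. Of 109 genes outside the family at 33 to 38 Mb of chromosome 17, 5 were at least 2-fold apart: H2-Ea-ps, Ltb (0 and 38 counts), H2-DMb2, Msh5 (13 and 52) and Col11a2 (184 and 86). B cells in the TKO library were argued against by the summed B cell marker count, 1635 in WT and 1739 in TKO, whose ratio had an upper bound of 1.13 (without Blnk, which macrophages also express, 28 and 16). A candidate explanation is a chromosome segment from another mouse strain around the MHC, left from a mixed breeding background, since C57BL/6 mice lack H2-L and express no H2-E α chain, although none of the deleted clusters lies on chromosome 17. The share of genes at least 2-fold apart outside class I was 1.87 times that elsewhere (4.59% against 2.45%), but with an interval of 0.615 to 4.24 the test leaves it open. Atp6v0c-ps2, whose parent gene lies on chromosome 17, was among the 3 of 17 processed copies at least 2-fold apart, and with Atp6v0c it had a summed count of 5242 in WT and 5531 in TKO.

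Stromal transcripts were lower, and 2 explanations were tested. The tables argue against a lower level of the whole extracellular matrix and protease set, which would need its members to fall about as the stromal markers did (median −0.96). The median of the 30 other matrix genes was −0.0352, with an interval of −0.29 to 0.15. Fewer stromal cells in the TKO culture could give part of this pattern: of 11 markers at 5 CPM or more in WT, 9 were lower and 0 higher beyond counting error. That explanation also predicts a fall by about a common factor, and the falls were unequal. The log2 ratio was −1.90 (−2.05 to −1.77) for Col1a1 but −0.92 (−1.17 to −0.71) for Acta2. Pdgfrb (478 and 510 counts) and Kitl (76 and 65 counts) were not lower beyond counting error. Whether macrophages supply some of these transcripts was not tested, so the explanation is neither borne out nor excluded. The genotype itself, culture and dissection cannot be told apart with 1 library each.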
